A study of Danio rerio with 8 samples.

How the data were processed

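The series holds 8 libraries from zebrafish liver, made from total RNA by 3' RNA-SAGE, with library construction by the standard protocol of the SOLiD platform, per the labels' protocols. Groups were taken from the sample titles and checked against the genotype and treatment labels: M-D-, M+D-, M-D+ and M+D+, 2 libraries each. M+ libraries carry the Myc transgene and D+ libraries were treated with doxycycline.

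Each deposited file lists a GI number, a RefSeq accession and a value in CPM (tags of a row relative to the library total), as normalized by the authors. The aligner, the reference build and the rule for assigning tags to transcripts are not given in the sources used here. The deposited CPM values of each library sum to the same total within rounding, and a transcript that a file does not list was taken as 0 tags. The values are whole multiples of 1 step per library, which is the worth of 1 tag. With that step, 100% of the low values (up to 20 tags) and at least 99.0% of all values came out as whole tags within 0.1, and this gave the library totals: 4402177 and 4611810 tags in M-D- libraries 1 and 2, 5020852 and 4524371 in M+D-, 1682372 and 4414590 in M-D+, and 6399852 and 2864061 in M+D+. The 50 most abundant rows took 53.1% (M-D+ library 1) to 71.2% (M+D+ library 1) of the tags of a library. Precision is lowest in M-D+ library 1, where 1 tag is worth 0.594 CPM. Counting limits cover counting error only, since tags are amplified and carry no molecular identifiers.

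Gene symbols came from the RefSeq gene table of assembly GRCz12tu by RefSeq accession and were used for names only. Of 15600 rows, 10410 had a symbol, and of the 4577 rows tested 3746 did (81.8%). The 831 tested rows without a symbol are in all counts and are not named. Of all rows, 122 have a GI number but no RefSeq accession and hold 1.25% to 4.72% of a library's tags. They were kept as rows, since each is a sequence record. Transcripts with near-identical 3' ends can share a tag, and how such tags were assigned is not given in the sources used here, so values of members of gene families (ribosomal proteins, globins, cytochromes P450) are uncertain in that respect. No coordinates are given, since the build behind the files is not known.

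The main test was limma 3.58.1 in R 4.3.3, fitted to log2(CPM + 1) with an intensity trend and without robust variance, on the deposited values with no further scaling. Rows needed at least 5 CPM in at least 2 of the 8 libraries. All 8 libraries entered 1 fit of 4 group means (4 residual degrees of freedom, 4.07 prior). Tests were two-sided, with Benjamini-Hochberg adjustment over the 4577 rows and a threshold of 0.05. The 7 comparisons were M+D+ against the mean of the 3 control groups, M+D+ against each control group, M+D- against M-D-, M-D+ against M-D-, and the interaction of genotype and doxycycline. Fold changes on the log2(CPM + 1) scale understate the change of rows with low values. Since the main test runs on CPM values, edgeR 4.0.16 (quasi-likelihood test with TMM factors) and DESeq2 1.42.0 (Wald test) were run on the recovered whole tags as alternatives. TMM factors computed on the deposited values were 1.71 and 1.42 in M-D+ libraries 1 and 2 and 0.701 and 0.857 in M+D+, against 0.817 to 0.961 in the other libraries.

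Gene lists (42 lists of pathways and cell type markers) were fixed before the data were examined, as were the comparisons, the list of other settings to try and the rule for naming genes. The deposited values decided between the count test and the limma test written for CPM values. Lists with at least 3 tested rows (38 lists) were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over lists within a comparison. Fry tests whether the rows of a list move on balance in 1 direction, or in either direction. In M+D+ against the mean of the controls it called 8 lists in the first sense and 32 in the second.

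Genes were named by this rule. For M+D+ against the mean of the controls, the 10 largest rises and 10 largest falls by log2 change were taken among called rows with a symbol, a mean of at least 20 CPM over the 8 libraries and both tumour libraries on the same side of all 6 control libraries. For each other comparison the 4 largest rises and 4 largest falls were taken by the same rule, with no such condition on sides for the interaction. For each list, up to 3 members that rose and 3 that fell with the smallest p were taken, or, if none passed, the 2 with the smallest p as values. The genes myca, mycb, mych, fabp10a and krt4 were always named where measured. Any gene named outside the rule is said to be so. For 2 genes taken by the rule the values are not reported here, and both stay in every count.

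Replicate libraries were compared by a chi-square test over rows. All pairs of libraries differed by more than sampling noise (chi-square per degree of freedom of at least 33.3), so none was counted as a repeat of another. The labels number the libraries of each group 1 and 2 and give no shared fish, day or batch behind a number. The fits were tested on simulated tags drawn for 4577 rows from the real means, library sizes and dispersions, with 50 rows changed at each fold size. For M+D+ against the mean of the controls, 2% of rows changed 2-fold, 70% of those changed 4-fold, 96% of those changed 8-fold and 100% of those changed 16-fold were recovered, and 9 of 144 calls were rows that had not been changed. The simulated changes went up and down in equal number from 1 shared set of means. The libraries of the data had TMM factors from 0.701 to 1.71, so this share of false calls does not carry over to calls on the deposited values. In a simulation with the 59 translation rows raised, camera called that list alone, at both correlations. The simulated rows were drawn independently, while the ribosomal protein rows of the data had an estimated correlation of 0.679. The simulation therefore does not show how camera fares, at either setting, with rows that move together.

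The other settings listed in advance were TMM scaling, quantile normalization, equal medians of the log values, values rescaled without the 50 most abundant rows, no filter or a mean of at least 20 CPM, pseudocounts of 0.5 and 5, robust limma, edgeR, the replicate number as a block, fits of the compared groups alone, each library left out in turn, rows of 1 gene summed, an added 2-fold threshold, and other control averages. 4 more were chosen after seeing the data: DESeq2, thinning every library to 1682372 tags, values re-formed without ribosomal protein and fabp10a rows, and the log2 level of esr1 as a covariate. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures.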

Results

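The livers of transgenic zebrafish in which doxycycline switches on a Myc gene were profiled by 3' RNA-SAGE, which counts a short tag near the 3' end of each transcript, on the SOLiD sequencer. The transgenic fish carry a liver (fabp10) promoter that drives a doxycycline-dependent transactivator, a Myc gene under that transactivator's control, and a krt4 promoter with a green fluorescent reporter. There were 4 groups of 2 libraries: wild-type siblings without doxycycline (M-D-), transgenic fish without doxycycline (M+D-), wild-type siblings on doxycycline (M-D+), and transgenic fish on doxycycline (M+D+), whose libraries the submitters call tumour samples. Doxycycline treatment began at 21 days after fertilization. Nothing in the labels used here says whether the 2 libraries of a group came from separate fish or pools, so the p-values below measure the spread between these libraries, which may be technical.

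Library totals, recovered from the deposited values, ran from 1682372 tags (M-D+ library 1) to 6399852 (M+D+ library 1), and the other libraries held 2864061 to 5020852 tags. A value of 0 allowed a level of up to 0.469 to 1.783 CPM (3 tags, counting error only). The values of 15600 transcript rows were listed in at least 1 library, and 4577 of them passed the filter on low values. Across rows, the log2 values of the 2 libraries of a group had a Pearson r of 0.961 (M-D-), 0.967 (M+D-), 0.891 (M-D+) and 0.927 (M+D+). Values below are CPM (tags of a row per library total, as scaled by the authors), given as mean ± SD of the 2 libraries of a group (n = 2), and log2 changes are on the log2(value + 1) scale with their standard error.

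The 71 measured rows of cytosolic ribosomal proteins took 45.7% ± 0.9 of all tags in M+D+, against 34.3% ± 4.0 in M-D-, 29.1% ± 3.7 in M+D- and 26.8% ± 9.3 in M-D+ (SD, n = 2 each). Both tumour libraries, at 45.1% and 46.3%, lay above all 6 control libraries, which ran from 20.2% to 37.1%. The difference of 15.7 percentage points had an exact two-sided permutation p of 0.0357, the smallest that 28 splits can give. This test was not among those fixed in advance. Its p restates that both tumour libraries stood highest, and it takes the 8 libraries as exchangeable, though those of a group may be technical repeats. The liver fatty acid-binding protein gene fabp10a alone took 7.9% to 21.0% of the tags of each library. CPM values are shares of a library, so counts after TMM scaling are given as well.

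**Figure D1:**
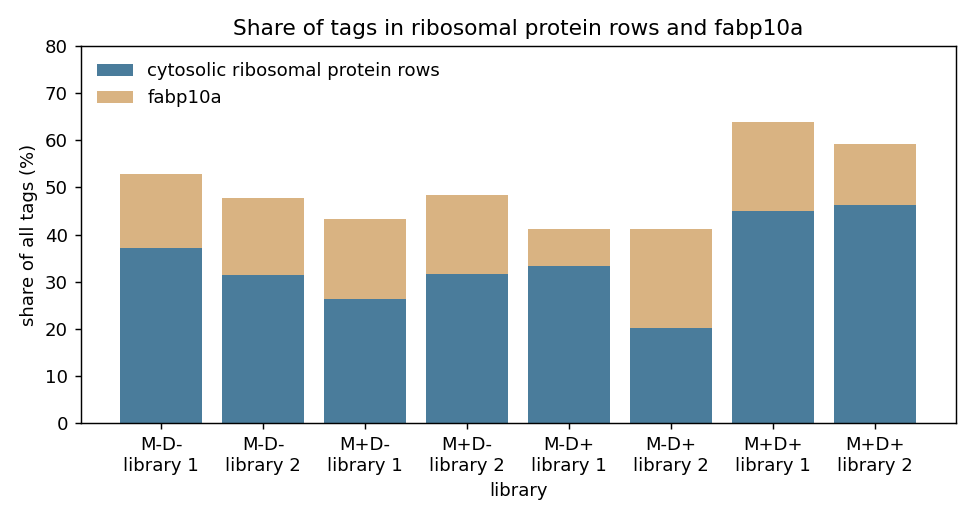
Share of all tags (%, vertical axis) in the 71 ribosomal protein rows (blue) and in fabp10a (tan), 1 bar for each of the 8 libraries on the horizontal axis. The tumour libraries reach 63.9% and 59.3% together, and the control libraries lie between 41.2% and 52.8%.

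The endogenous genes related to the transgene were read first. Levels of mycb were 72.2 ± 2.2 in M-D-, 24.025 ± 4.9 in M+D-, 68.6 ± 65.3 in M-D+ and 13.3 ± 15.7 in M+D+, with a log2 change of -2.34 ± 0.80 in tumours against the mean of the controls (limma adjusted p = 0.0671). For mych the change was -1.62 ± 0.68 (limma adjusted p = 0.113), and myca did not reach the filter. These are rows of endogenous zebrafish transcripts, and which Myc coding sequence the transgene holds is not stated in the labels, so they do not check the transgene. The change was 0.05 ± 0.41 for fabp10a and -0.02 ± 0.49 for krt4 (limma adjusted p = 0.941 and 0.975). The sign of krt4 turned positive under TMM scaling (0.39), and that of fabp10a turned negative without M+D+ library 1 (-0.22). The value of mycb passed without M-D+ library 2 and without M+D+ library 2.

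Tumour livers (M+D+) were first set against the mean of the 3 control groups. The largest rise was in pabpc4 (NM_201296), a cytoplasmic poly(A)-binding protein, at 6028 ± 1116 in M+D+ against 79.0 ± 4.6 in M-D-, 971 ± 644 in M+D- and 130.1 ± 18.6 in M-D+, a log2 change of 4.85 ± 0.38 (28.8-fold, limma adjusted p = 0.00341). It was followed by the ribosomal protein genes rps6 (log2 change 3.60), rpl12 (3.58), rpl4 (3.39) and rpl22 (3.13), and by tpt1 (3.15), the translationally controlled tumour protein. As an example, rps6 stood at 1395 ± 585 in M+D+ and at 122.8 ± 31.3, 105.8 ± 20.52 and 106.7 ± 46.7 in M-D-, M+D- and M-D+. Other large rises were in the complement component c3a.2 (5.23-fold), the stress-response gene sesn1 (4.28-fold) and the phosphoglycerate mutase gene pgam2 (4.09-fold). The largest falls were in hsd11b2, which inactivates cortisol (27.9-fold lower), the secreted phospholipase pla2g3 (18.1-fold), apoa1a, the main protein of high-density lipoprotein (17.4-fold), the mitochondrial carrier slc25a48 (13.2-fold) and zgc:92749 (13.1-fold). They were followed by ifi27.1 (log2 change -3.59), the thyroid hormone deiodinase dio2 (11.4-fold), the prolyl hydroxylase p4ha3 (10.3-fold), the prolyl isomerase fkbp3 (8.18-fold) and the protease inhibitor serpinb1 (8.08-fold). Levels of apoa1a were 108 ± 67.1 in M+D+ and 1635 ± 63, 1430 ± 33 and 2400 ± 1501 in M-D-, M+D- and M-D+, a log2 change of -4.12 ± 0.44.

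The 20 genes taken by the rule, 10 rises and 10 falls, had limma adjusted p-values from 0.00341 to 0.0149. The rule took only genes with both tumour libraries beyond all 6 control libraries. All 20 stayed called after TMM scaling, and 17 of them, 10 rises and 7 falls, by edgeR's quasi-likelihood test on the recovered tags. The falls lost there were pla2g3, dio2 and p4ha3 (edgeR adjusted p = 0.0564, 0.0738 and 0.068). Their values in M+D+ libraries 1 and 2 were 0 and 3.84 for pla2g3, 10.78 and 94.62 for dio2, and 1.88 and 12.57 for p4ha3. In fits that left out 1 library at a time, 9 of the 20 passed in every fit: pabpc4, rps6, rpl12, rpl4, tpt1, rpl22, pgam2, apoa1a and zgc:92749. The other 11 lost the call without M+D+ library 1, and serpinb1 also without M+D+ library 2. Over all 4577 rows, limma called 1052 at an adjusted p below 0.05, 106 higher and 946 lower (89.9% lower), and the median log2 change of all rows was -0.57. After TMM scaling it called 507, 241 higher and 266 lower (52.5% lower), with a median of -0.13, and 372 rows were called in the same direction both ways. EdgeR called 449 rows, 300 higher and 149 lower. Without M-D- library 1 or 2 the count was 682 or 551, without M+D- library 1 or 2 it was 435 or 469, and without M+D+ library 1 or 2 it was 67 or 522.

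**Figure D2:**
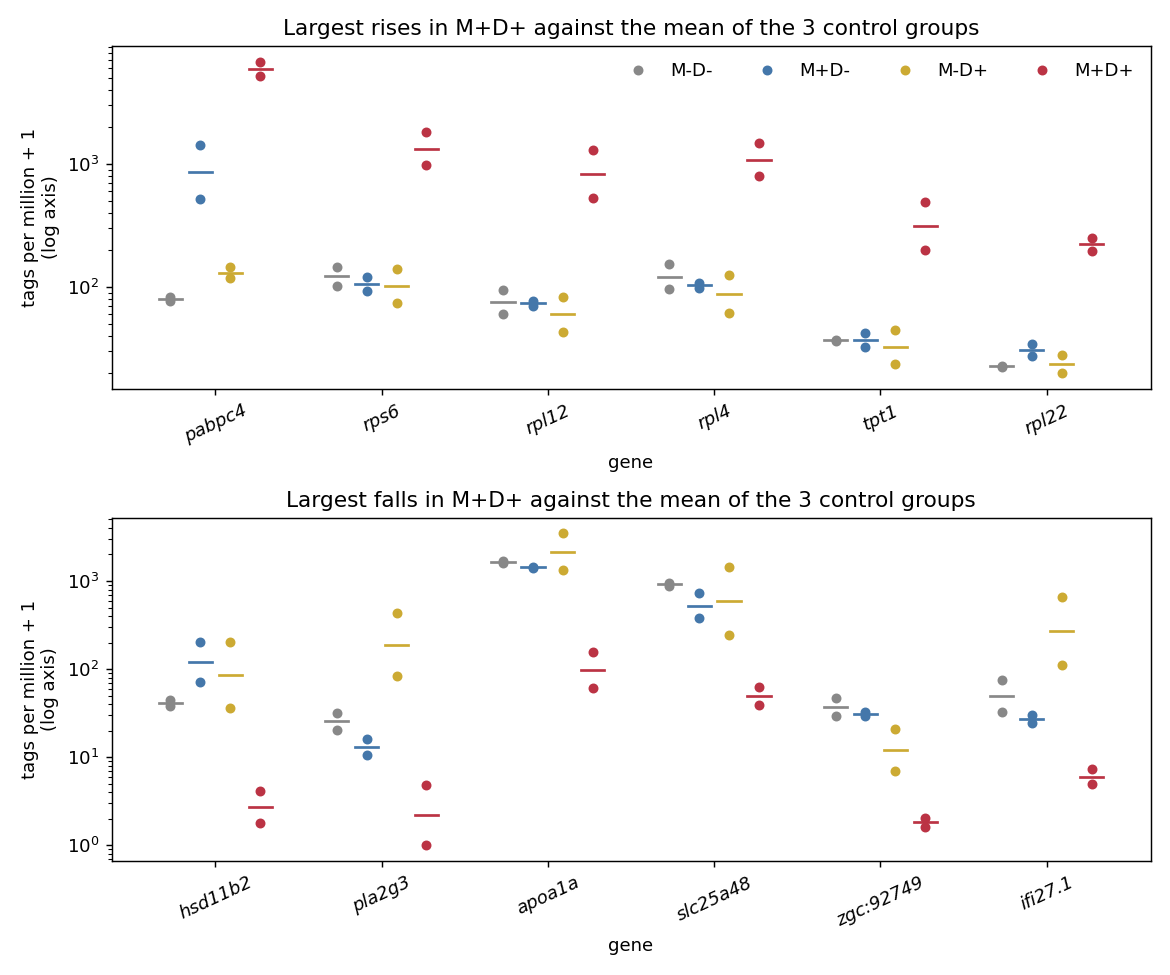
CPM plus 1 (vertical log axis) of the 6 largest rises (top) and 6 largest falls (bottom) in M+D+, with 1 dot per library, colours for the 4 groups and a short line at each group's geometric mean. By the rule that took these genes, both M+D+ dots lie above all control dots for the rises, as for pabpc4, and below them for the falls, as for apoa1a.

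Genes of protein synthesis were described by list. Of 71 ribosomal protein rows, 16 rose and none fell (18 rose adjusted over the list alone). Both tumour libraries were above all 6 controls in 42 of them, where chance order gives 3.57% for a single row. These rows move together (estimated correlation 0.679), so the 42 are not separate draws against that value. The 3 with the smallest p were rpl22, rps6 and rpl4. Of 59 rows of translation initiation and elongation factors, 7 rose and 7 fell (7 and 8 adjusted over the list alone). Those that rose included pabpc4, the 4E-binding protein gene eif4ebp3l (34.9 ± 2.5 in M+D+ and 5.1 ± 1.7 in M-D-) and eif3c (46.0 ± 23.9 and 15.0 ± 0.3). Those that fell included the helicases eif4a1a and eif4a2 and the cap-binding eif4e2. Of 40 ribosome biogenesis rows 1 rose, the nucleolar helicase ddx21 (446 ± 100 in M+D+ against 129.7 ± 87.3 to 225.4 ± 39.7 in the control groups), and 7 fell (1 and 6 adjusted over the list alone), among them nucleolin, ncl (132.7 ± 3.5 against 462.6 ± 99.1 to 525.3 ± 197.7), grwd1 and bysl. Among 13 cytosolic tRNA synthetases 2 fell, cars1 and sars1, and none rose (the same adjusted over the list alone). After TMM scaling 41 ribosomal protein rows rose and none fell, 12 translation factors rose and 2 fell, 2 ribosome biogenesis rows rose and 2 fell, and 1 tRNA synthetase fell. The calls left in these 4 lists without M+D+ library 1 were 5 rises of ribosomal proteins and 2 of translation factors. Those left without M+D+ library 2 were 4 rises of ribosomal proteins, 2 rises and 4 falls of translation factors and 2 falls each of ribosome biogenesis rows and tRNA synthetases. With M-D+ left out of the control average these were 9 rises, 3 rises and 2 falls, and 1 fall, and no tRNA synthetase was called.

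In camera tests with a preset correlation of 0.01, the ribosomal protein list moved up relative to all other rows (adjusted p = 1.97e-36, median log2 change 0.70), as did the translation factors (adjusted p = 0.00978). The median of the translation factors was -0.33, below 0 but above the median of all rows. With an estimated correlation no list was called in this comparison, and the adjusted p was 0.876 for both lists. Fry in 1 direction called neither the ribosomal protein list (adjusted p = 0.0957) nor the translation factors (adjusted p = 0.689). Camera called 5 lists in all, and 9 without M+D+ library 2. Of the 160 calls of named genes over all comparisons, 40 passed without M+D+ library 1 and 111 without M+D+ library 2.

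The next lists hold genes of liver metabolism and secreted proteins. Of 28 rows of fatty acid oxidation and peroxisomes 13 fell and none rose (14 fell adjusted over the list alone), among them acadvl and decr1, a reductase for unsaturated fatty acids, which stood at 11.3 ± 5.8 in M+D+ against 71.1 ± 18.7 in M-D-. Of 40 rows of bile acid and xenobiotic metabolism 16 fell and none rose (24 fell adjusted over the list alone), among them fmo5, cyp2x9 (72.4 ± 11.7 against 517 ± 108 in M-D-) and gstr. Of 35 secreted plasma protein rows 14 fell and none rose (17 fell and 1 rose adjusted over the list alone), with apoa1a, ahsg2 (372 ± 162 against 2078 ± 507 in M-D-) and itih3a.1 in front. Of 28 complement and coagulation rows 2 rose, c3a.2 and c3b.1, and 8 fell (2 and 11 adjusted over the list alone), including the lectin hbl4, c8g and c1s.2. Of 15 gluconeogenesis and glycogen rows 3 fell and none rose (the same adjusted over the list alone): g6pc1a.2, a glucose-6-phosphatase (156.6 ± 9.2 against 756 ± 9 in M-D-), pgm1 and g6pc1a.1. Of 15 glycolysis rows 2 rose, ldhba (15.2 ± 5.2 against 1.7 ± 0.1 in M-D-) and eno1a, and 1 fell, tpi1b (the same adjusted over the list alone).

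Among 43 rows of amino acid breakdown and the urea cycle 2 rose, ass1 and arg2, and 4 fell (none and 2 adjusted over the list alone), including tdo2b, which opens the tryptophan ring, amdhd1 and got2a. Among 19 rows of lipid and cholesterol synthesis 5 fell and none rose (the same adjusted over the list alone), led by elovl6, elovl2 and nsdhl. Of 22 rows of nucleotide and polyamine synthesis 5 fell and none rose (the same adjusted over the list alone), with oaz1a, hprt1 and rrm2l in front. None of these 9 metabolic and secretory lists passed camera on the deposited values, and bile acid and xenobiotic metabolism passed after TMM scaling (adjusted p = 0.0434). With an estimated correlation its adjusted p was 0.876. Fry in 1 direction, on the deposited values, called fatty acid oxidation lower (adjusted p = 0.0304), as well as bile acid and xenobiotic metabolism (adjusted p = 0.0286). It also called secreted plasma proteins and lipid synthesis lower (adjusted p = 0.0343 each). Unlike camera, fry does not set a list against the other rows, and the median log2 change of all rows was -0.57. After TMM scaling 2 fatty acid oxidation rows rose and 4 fell, and the rises and falls were 1 and 10 for bile acid and xenobiotic metabolism, 1 and 5 for plasma proteins, 3 and 2 for complement, 3 and 1 for gluconeogenesis, 2 and none for glycolysis, 3 and 1 for amino acid breakdown, 1 and 2 for lipid synthesis and none and 1 for nucleotide synthesis. The calls left without M+D+ library 1 were 2 falls each for fatty acid oxidation and bile acid metabolism, 1 each for plasma proteins and complement, and 2 rises for glycolysis. The falls without M+D+ library 2 numbered 8 for fatty acid oxidation, 17 for bile acid metabolism, 10 for plasma proteins, 3 for complement, 2 for gluconeogenesis, 4 for amino acid breakdown, 2 for lipid synthesis, 1 for nucleotide synthesis and 0 for glycolysis, and 1 row each rose in complement, glycolysis and amino acid breakdown. With M-D+ left out of the control average the falls were 8, 10, 8, 4, 2, 2, 1, 1 and 0 in the same order, and 1 row each rose in those 3 lists. Median and mean log2 changes differed in sign for glycolysis (-0.27 and 0.06) and gluconeogenesis (0.25 and -0.09).

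Among mitochondrial and protein-handling genes, the 68 nuclear-encoded rows of oxidative phosphorylation went both ways. Of them 5 rose, including the cytochrome c oxidase subunits cox7b, cox6a2 (82.5 ± 9.0 in M+D+ against 26.9 ± 4.7 in M-D-) and cox6a1, and 9 fell, including atp5mc3a, ndufb6 and cycsb (5 and 7 adjusted over the list alone). Camera placed the list above other rows (adjusted p = 0.0117, and adjusted p = 0.876 with an estimated correlation), while its median log2 change was -0.15. Without M+D+ library 2 the call was lost. After TMM scaling 9 of its rows rose and 2 fell, so that the larger number turned from falls to rises, and the rises and falls were 2 and none without M+D+ library 1, 3 and 6 without M+D+ library 2, and 5 and 2 with M-D+ left out of the control average. Of 44 mitochondrial ribosomal protein rows 11 fell and none rose (13 fell adjusted over the list alone), with mrpl24, mrpl48 and mrpl19 in front. After TMM scaling 1 rose and 8 fell, and the falls were 0 and 6 without M+D+ library 1 and 2 and 5 with M-D+ left out. Of 39 proteasome rows 17 fell and none rose (24 fell adjusted over the list alone), as for psmc1b, psmd2 and psmd4a. Camera called the list lower (adjusted p = 0.0247, and adjusted p = 0.876 with an estimated correlation), and the call was lost after TMM scaling (adjusted p = 0.0516) and without M+D+ library 1. With M-D+ left out of the control average 0 proteasome rows were called, and after TMM scaling 2 were. Without M+D+ library 1 no row of this list and none of the next was called, and without M+D+ library 2 the counts were 10 and 13 falls. Of 47 rows of folding and secretion in the endoplasmic reticulum 16 fell and none rose (18 fell adjusted over the list alone), among them tmed2, the disulfide isomerase p4hb (42.0 ± 23.002 against 236 ± 115 in M-D-) and spcs1. With M-D+ left out of the average 3 of these fell, and after TMM scaling 6. Camera did not call this list on the deposited values (adjusted p = 0.0592) and called it lower after TMM scaling (adjusted p = 0.00477), with adjusted p = 0.876 with an estimated correlation on the deposited values. Of 32 chaperonin and heat shock rows 4 rose, including cct8, hsp90ab1 (556 ± 177 against 252.8 ± 83.6 in M-D-) and cct2, and 8 fell, including fkbp5, dnaja2a and trap1 (the same adjusted over the list alone). After TMM scaling 4 rose and 1 fell, with M-D+ left out of the average 2 rose and 2 fell, and none and 2 of these fell without M+D+ library 1 and 2, with no rise.

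Few rows of the cell division lists passed the filter. Of 9 rows of S phase and DNA replication 3 fell, gmnn, rpa2 and rrm2l, and of 6 rows of G2 and mitosis 3 fell, tuba8l4, hmgb2a and prc1a, with no rise in either (4 and 4 fell adjusted over the list alone). Among 24 rows of the p53 response and apoptosis 1 rose, sesn1, and 7 fell, with tnfrsf1a, casp6a and sesn3 in front (1 and 9 adjusted over the list alone). Among 47 splicing and RNA processing rows 1 rose, sf3b2, and 14 fell, with hnrnpa0b, prpf38a and lsm7 in front (1 and 21 adjusted over the list alone). In the ATF4 and amino acid response list (18 rows) 1 rose, sesn1, and 1 fell, cbsa. In the invasion list (16 rows) 2 fell, twist1b (218 ± 11 in M+D+ against 1631 ± 360 in M-D-) and cdh2, and none rose. In iron handling (10 rows) 1 rose, the iron exporter slc40a1, and 3 fell, fth1b, fth1a and hmox1a. In the interferon and acute phase list (13 rows) 3 fell, ifi27.1, b2m and rsad2, and none rose. In these last 4 lists the counts were the same adjusted over the list alone. After TMM scaling the rises and falls were none and 1 for S phase, none and 2 for G2 and mitosis, 2 and 2 for the p53 response, 1 and 3 for splicing, 1 and 1 for the ATF4 response, iron handling and interferon lists, and none and 1 for invasion. The 1 call left in these 8 lists without M+D+ library 1 was a fall in the p53 list. The falls without M+D+ library 2 were 0 for S phase, 2 for G2 and mitosis, 2 for p53, 6 for splicing, 1 for ATF4, 2 for invasion, 2 for iron and 3 for interferon, and 1 row rose in the p53 and ATF4 lists. With M-D+ left out of the control average the falls were 1, 3, 2, 4, 0, 1, 1 and 0 in the same order, and 1 row rose in the p53, ATF4 and iron lists. No row of the mitochondrially encoded list was measured.

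Markers of other cell types were read beside these groups. Of 18 exocrine pancreas rows 6 fell and none rose (9 fell adjusted over the list alone), including the elastase ela2l, sycn.2 and the amylase amy2al1, and of 3 endocrine pancreas rows 1 fell, sst1.1. Of 8 erythrocyte rows 1 rose, alas2, and 3 fell, hemgn and the globins hbba1 and ba1l. Of 17 macrophage rows 1 rose, slc40a1, which is also in the iron list. Camera called the macrophage list up (adjusted p = 0.0218, and adjusted p = 0.876 with an estimated correlation), with a median log2 change of -0.10 and a mean of 0.09. Without M+D+ library 1 the call was lost. Of 5 neutrophil rows 2 rose, lta4h and arg2, and 1 fell, cpa5 (median -0.32, mean 0.08), and of 3 endothelial rows 1 rose, id1, and 1 fell, ramp2. Like the pancreas row ela2l, cpa5 was highest in M-D- library 1 (346.65 CPM, and 130.16 for ela2l). Both were lowest in M+D+ library 1 (60.63 and 16.72 CPM). The fall of cpa5 therefore cannot be told apart from that of the exocrine pancreas rows. Adjusted over the list alone, 2 neutrophil rows rose and 2 fell, and 1 endothelial row rose and 2 fell. Of 16 biliary and progenitor rows 6 fell, including igf2b, prox1a and cldn15la, and of 8 stellate and fibroblast rows 1 fell, pcolcea (7 and none adjusted over the list alone). The muscle list (8 rows) had 1 rise, pgam2. Of the 2 lymphocyte rows il7r fell (1081 ± 477 in M+D+ against 2675 ± 323 in M-D-), and of the 2 testis rows odf3l2a fell, being listed at 0 in both tumour libraries. In M-D- the il7r row stood above apoa1a (1635 ± 63 CPM), so whether it marks lymphocytes here stays open. For the erythrocyte, endocrine pancreas, macrophage, muscle, lymphocyte and testis lists the counts were the same adjusted over the list alone. After TMM scaling 3 exocrine pancreas rows, 1 erythrocyte row and 1 biliary row fell, 1 erythrocyte, 2 macrophage, 2 neutrophil, 1 endothelial and 1 muscle row rose, and nothing else in these lists was called. The calls left without M+D+ library 1 were the rise in the muscle list and 1 fall in the endocrine pancreas list. The falls without M+D+ library 2 were 3 in the exocrine pancreas, 3 in the erythrocyte, 1 in the biliary and 1 in the lymphocyte list, and 1 endothelial and 1 muscle row rose. With M-D+ left out of the control average the falls were 5, 2, 2 and 1 in those lists and 1 in the endothelial list, and 1 erythrocyte, 2 macrophage, 1 neutrophil, 1 endothelial and 1 muscle row rose.

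No member was called in the intestine (16 rows), skin and keratin (6 rows), oocyte and ovary (5 rows) and female liver (2 rows) lists. Their members with the smallest p, with log2 changes, were cyp3a65 (-1.37 ± 0.46) and rbp2a (-0.70 ± 0.25), krt5 (-0.92 ± 0.61) and krt91 (-0.53 ± 0.38), rnasel2 (-1.61 ± 0.52) and zp3b (-1.59 ± 0.60), and esr1 (-1.30 ± 1.17) and zp3a.1 (-0.46 ± 0.98). No member was called adjusted over the list alone either. The signs of krt91 and zp3a.1 turned under quantile normalization and equal medians. That of esr1 turned without M+D+ library 1 (0.64), and cyp3a65 and rnasel2 passed without M-D+ library 1. The estrogen receptor gene esr1 stood at 12.3 and 23.85 in the M-D- libraries 1 and 2, at 1.6 and 5.8 in M+D-, at 129.0 and 8.4 in M-D+ and at 0.5 and 20.6 in M+D+, so the 2 libraries of the 2 doxycycline groups were far apart.

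The comparison of M+D+ with M-D+ sets transgenic against wild-type fish, both on doxycycline. The largest rises were in pabpc4 (log2 change 5.52 ± 0.46), rpl12 (3.79 ± 0.50), rps6 (3.70 ± 0.43) and rpl4 (3.63 ± 0.45). The largest falls were in pla2g3 (-6.43 ± 0.88), ifi27.1 (-5.51 ± 0.77), dio2 (-5.09 ± 0.83) and hsd11b2 (-4.99 ± 0.83). Limma adjusted p-values of these 8 genes were 0.00501 or lower. In the ribosomal protein list 22 of 71 rows rose and 1 fell, in the proteasome list 31 of 39 fell, and in the list of folding and secretion in the endoplasmic reticulum 34 of 47 fell. Adjusted over the list alone the counts were 12 rises and no fall, 33 falls and 37 falls, and after TMM scaling 61 rises and no fall, 12 falls and 20 falls. Camera called all 3 (adjusted p of 3.1e-47, 0.000284 and 0.000284), and with an estimated correlation none was called (lowest adjusted p = 0.652 over 38 lists). Limma called 2023 rows, 114 higher and 1909 lower (94.4% lower), and after TMM scaling 688, 354 higher and 334 lower (48.5% lower). Without M+D+ library 1 the count was 1057.

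The comparison of M+D+ with M+D- sets transgenic fish on and off doxycycline. The largest rises were in rps6 (3.66 ± 0.43), rpl12 (3.49 ± 0.50), rpl4 (3.39 ± 0.45) and tpt1 (3.08 ± 0.48), and the largest falls in hsd11b2 (-5.47 ± 0.83), tdo2b (-5.00 ± 1.005), zgc:92749 (-4.07 ± 0.52) and apoa1a (-3.86 ± 0.54). Levels of tdo2b were 14.5 ± 17.5 in M+D+ and 323 ± 163 in M+D-, and the limma adjusted p-values of these 8 genes ran from 0.0166 to 0.0438. Secreted plasma proteins had 3 falls among 35 rows and bile acid and xenobiotic metabolism 6 among 40 (19 and 18 adjusted over the list alone, 3 and 3 after TMM scaling), and camera called both lists lower (adjusted p = 8.11e-05 and 0.00499). The ribosomal protein list was called higher (4 of 71 rows rose, 6 adjusted over the list alone, 5 after TMM scaling, adjusted p = 7.67e-25), and all 3 had an adjusted p = 0.924 with an estimated correlation. Limma called 125 rows, 18 higher and 107 lower (85.6% lower), and after TMM scaling 78, 23 higher and 55 lower (70.5% lower). The count was 12 without either M-D- library, 1 and 0 without M+D- library 1 and 2, 261 and 239 without M-D+ library 1 and 2, and 14 without M+D+ library 1.

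The comparison of M+D+ with M-D- sets tumour livers against those of untreated wild-type siblings. Large rises were in pabpc4 (6.22 ± 0.46), rpl12 (3.46 ± 0.50) and rps6 (3.45 ± 0.43), and the largest falls in tdo2b (-4.94 ± 1.005), zgc:92749 (-4.35 ± 0.52), slc25a48 (-4.21 ± 0.74) and apoa1a (-4.05 ± 0.54). The limma adjusted p-values of these 7 genes ran from 0.00363 to 0.0377. The macrophage list was called higher by camera (2 of 17 rows rose, 3 adjusted over the list alone, 3 after TMM scaling, adjusted p = 0.000164) and the exocrine pancreas list lower (3 of 18 fell, 8 adjusted over the list alone, 2 after TMM scaling, adjusted p = 0.006), and both had an adjusted p = 0.925 with an estimated correlation. Limma called 239 rows, 62 higher and 177 lower (74.1% lower), and after TMM scaling 246, 121 higher and 125 lower (50.8% lower). No row was called without either M-D- library, 54 and 53 without M+D- library 1 and 2, 433 and 432 without M-D+ library 1 and 2, and 11 and 104 without M+D+ library 1 and 2.

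Across the comparisons of M+D+ with each control group, 15 rows were called higher in all 3 and 63 lower in all 3, and after TMM scaling 19 and 28. Independent lists of those sizes would share 0.006 and 1.73 rows, and 20 simulations of unchanged groups that shared the M+D+ libraries gave 0 in each direction. Part of the excess over independent lists may come from the shared M+D+ libraries, since that value leaves out the sharing. The simulated value leaves out the effects. With no row changed few calls can arise in any comparison, so it is no measure for the overlap.

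The comparison of M+D- with M-D- asks what the transgene changes without doxycycline. Limma called 0 of 4577 rows, with 419 at an unadjusted p below 0.05, and edgeR called 0, with 464. After TMM scaling limma also called 0, with 497 at an unadjusted p below 0.05, whereas DESeq2 on the recovered tags called 36. A fit of these groups alone called 6, and leaving out M+D- library 1 gave 1. Camera called 16 lists, 7 up and 9 down, among them ribosome biogenesis down (40 rows, median log2 change -0.39, adjusted p = 0.00107), folding and secretion in the endoplasmic reticulum down (47 rows, median -0.55, adjusted p = 0.000403) and oocyte and ovary down (5 rows, median -2.61, adjusted p = 0.00692). With an estimated correlation no list was called (lowest adjusted p = 0.837). Adjusted over the list alone, 3 oocyte and ovary rows fell. Levels of the egg coat gene zp3b, chosen after its values were seen, were 16.985 ± 12.8 in M-D- and 1.8 ± 0.3 in M+D-. The egg coat gene zp3a.1, also chosen after its values were seen, stood at 6.59 and 42.72 in M-D- libraries 1 and 2, at 34.48 in M-D+ library 1 and at 15.36 in M+D+ library 2, against 0.88 to 4.98 in the other 4 libraries, and the M-D- libraries are among 4 that stand apart across the groups.

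The comparison of M-D+ with M-D- asks what doxycycline changes without the transgene. On the deposited values the largest rises were in dhrs11b.2, a short-chain dehydrogenase (4.15 ± 0.83), the endoplasmic reticulum chaperone genes dnajb11 (3.18 ± 0.55) and calr (2.74 ± 0.57), and homeza (2.98 ± 0.31). Levels of dnajb11 were 68.5 ± 34.3 in M-D+ and 6.3 ± 1.8 in M-D-. The largest falls were in cyp24a1, which breaks down active vitamin D (-4.98 ± 1.15), cst14a.2 (-3.82 ± 0.68), the creatine synthesis gene gatm (-2.70 ± 0.51) and the clock gene nr1d1 (-1.84 ± 0.34). Limma adjusted p-values of these 8 genes ran from 0.0232 to 0.0461, and after TMM scaling none was below 0.0503. The lists of folding and secretion in the endoplasmic reticulum (16 of 47 rows rose, 33 adjusted over the list alone) and the proteasome (18 of 39 rose, 31 adjusted over the list alone) were called higher by camera (adjusted p = 9.2e-05 and 2.05e-05), with adjusted p = 0.81 and 0.703 with an estimated correlation. After TMM scaling no row of either list rose.

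Limma called 448 rows in M-D+ against M-D-, 422 higher and 26 lower (5.8% lower), with a median log2 change of 0.72 over all rows. After TMM scaling 1 row was called, lower, and it has no gene symbol or RefSeq accession (GI 283436089, 49.8 and 41.4 in M-D- libraries 1 and 2 against 2.4 and 0.7 in M-D+). EdgeR called 0 rows, with 822 at an unadjusted p below 0.05, and DESeq2 on the recovered tags called 148, 39 higher and 109 lower. No row was called without any 1 of the M-D- or M+D- libraries, 110 without M-D+ library 1, and 161 and 183 without M+D+ library 1 and 2.

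The interaction asks whether doxycycline acted differently in transgenic and wild-type fish. The largest positive differences were in rps6 (log2 difference 3.90 ± 0.61), rpl4 (3.87 ± 0.64), rpl12 (3.83 ± 0.71) and tpt1 (3.26 ± 0.68). The effect of doxycycline on rps6 was 3.66 in transgenic fish (limma adjusted p = 0.0166) and -0.25 in wild-type fish (adjusted p = 0.686). The largest negative differences were in hsd11b2 (-6.52 ± 1.17), dhrs11b.2 (-5.59 ± 1.18), pla2g3 (-5.46 ± 1.25) and dio2 (-5.33 ± 1.18). For dhrs11b.2 the effect was -1.44 in transgenic fish (adjusted p = 0.362) and 4.15 in wild-type fish (adjusted p = 0.0397). Of 71 ribosomal protein rows 4 were called, all positive (the same adjusted over the list alone and after TMM scaling), and camera called the list (adjusted p = 3.08e-50, and adjusted p = 0.872 with an estimated correlation).

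Limma called 377 rows for the interaction, 12 positive and 365 negative (96.8% negative), with limma adjusted p-values from 0.0412 to 0.0467 for the 8 genes above. After TMM scaling 5 rows were called, all positive: rps6, rpl4, rpl12, rpl22 and caprin1b, of which the last 2 are named after their values were seen. EdgeR called 0, with 707 at an unadjusted p below 0.05, and DESeq2 called 164, 122 positive and 42 negative. No row was called without either M-D- library, M+D- library 2 or M+D+ library 1, 1 was called without M+D- library 1, and 202 without M+D+ library 2.

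**Figure D3:**
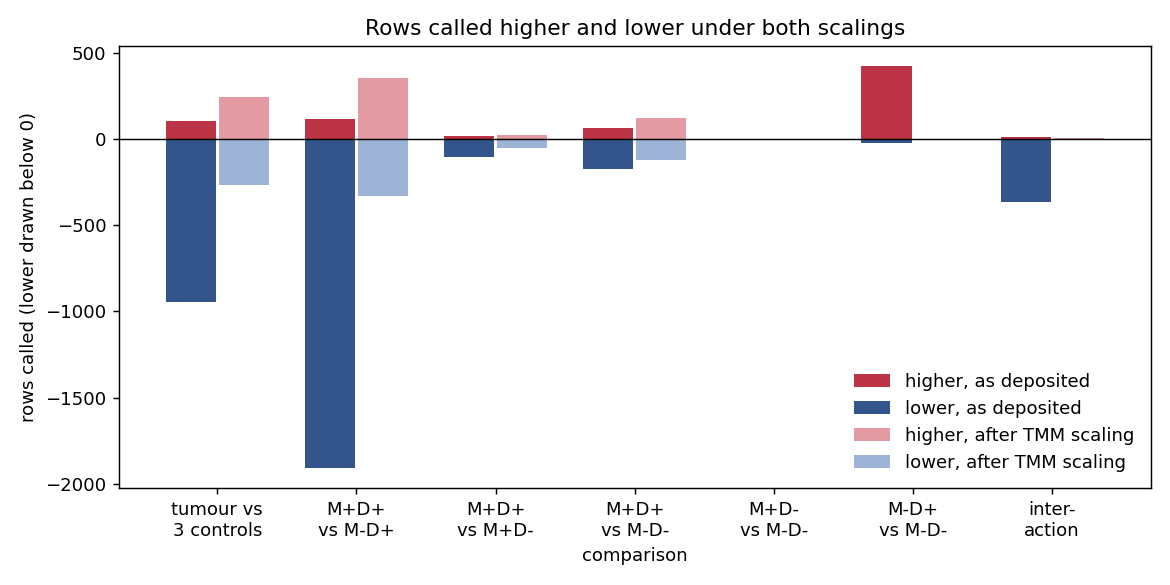
Number of rows called higher (red, above 0) and lower (blue, below 0) on the vertical axis for each of the 7 comparisons on the horizontal axis, on the deposited values (dark) and after TMM scaling (light). In M+D+ against M-D+ the calls were 114 higher and 1909 lower as deposited and 354 higher and 334 lower after scaling.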

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

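The tests of composition, depth, counting error and level, and the use of the fit without M-D+ as a test of the imbalance, were chosen only after the result was seen, though what composition and depth should show was written down before those 2 tests were run.

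Doxycycline had different effects in transgenic and wild-type fish by limma's test of the interaction in 377 rows on the deposited values, 12 positive and 365 negative. The log2 differences of the named genes were 3.905 for rps6, 3.87 for rpl4, 3.828 for rpl12, 3.259 for tpt1, -6.523 for hsd11b2, -5.594 for dhrs11b.2, -5.457 for pla2g3 and -5.332 for dio2. After TMM scaling 5 rows were called, all positive, and of these 8 genes rps6, rpl4 and rpl12 passed. EdgeR called 0 rows, with 707 at an unadjusted p below 0.05. Limma called 0 without ribosomal protein and fabp10a rows, with 760 at an unadjusted p below 0.05.

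Most rows called in the tumour libraries against the controls were lower in CPM (89.9%). Unequal counting noise from depth is argued against: with all libraries thinned to 1682372 tags, 90.6% of the called rows were lower. Thinning keeps the expected share of each row, so it cannot test an effect of depth on the shares themselves. The M-D+ libraries as the whole cause are argued against as well, since 82.0% were lower with M-D+ left out of the control average. A larger share of ribosomal protein tags may account for part of the imbalance in this comparison. The level of fabp10a itself changed little in the tumours (log2 change 0.05 ± 0.41). Without the 50 most abundant rows, a setting listed in advance, 77% of the 579 called rows were lower. With the ribosomal protein and fabp10a rows removed together and values formed anew, 58.1% of the called rows were lower. That step cannot tell their parts from each other. After the same step the shares were 79.9% in M+D+ against M-D+ (94.4% before), 55% against M+D- (85.6% before) and 39% against M-D- (74.1% before), and a real overall fall of other transcripts in the tumours stays open, as values CPM give no absolute amounts.

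The rows of rps6, rpl4, rpl12 and rpl22, and of tpt1, which is not in the ribosomal protein list, rose by at least 3.13 on the log2 scale. The other 67 ribosomal protein rows had a median of 0.69 and a highest value of 1.95. Counting error alone is argued against for the rise of the 5 rows over the controls. In each, the lower bound of the lower tumour library was at least 3.43 times the upper bound of the highest control library. These rows were named for their large rises, and the bound does not test their gap to the other ribosomal protein rows. A low level of the row as such stays open: the other ribosomal protein rows at 18 to 200 CPM in the controls, 4 in number, had a highest value of 1.921 and a median of 1.41, above that of all 67. As no ribosomal protein row of any level outside the 5 came within 1 log2 unit of them, the rows of this level could not have given another outcome. Tags shared with near-identical transcripts were not tested and stay open as well, beside a stronger response of these genes to Myc in the transgenic fish on doxycycline.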

How the results depend on the processing

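The alternatives chosen only after the data were seen were DESeq2, thinning to 1 depth, removal of ribosomal protein and fabp10a rows, and the esr1 covariate. Of the 160 calls of named genes, 108 passed after TMM scaling, 88 with edgeR and 40 without M+D+ library 1, and no called value turned in direction under any alternative run. Robust limma, summing rows of 1 gene and the added 2-fold threshold moved no count by over 1.5 times. The library with the fewest tags limits rows with low values. DESeq2 size factors inside edgeR were not run, being planned only for deposited counts. The cause of each shift below was not tested, except where the alternative itself uses fewer libraries or rows.

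Counts are given in the order M+D+ against the mean of the controls, against M-D+, against M+D-, M-D+ against M-D-, and the interaction, where the main counts were 1052, 2023, 125, 448 and 377. They were 507, 688, 78, 1 and 5 after TMM scaling, 366, 517, 49, 6 and 4 after quantile normalization, 456, 668, 75, 29 and 6 with equal medians of log values, and 579, 1023, 72, 0 and 10 without the 50 most abundant rows. They were 449, 601, 39, 0 and 0 with edgeR on the recovered tags, 534, 705, 208, 148 and 164 with DESeq2 on the recovered tags, and 408, 797, 40, 0 and 0 without ribosomal protein and fabp10a rows. DESeq2 called 36 in M+D- against M-D-. Beside the counts of 0, limma gave 1264 rows at an unadjusted p below 0.05 for M-D+ against M-D- without the 50 most abundant rows, and 1224 and 760 for M-D+ against M-D- and the interaction without ribosomal protein and fabp10a rows. EdgeR gave 822 and 707.

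With no filter on low values the counts were 556 against the mean of the controls, 66 against M+D-, 87 against M-D-, 3 in M-D+ against M-D- and 0 for the interaction (2530 at an unadjusted p below 0.05). With a mean of at least 20 CPM they were 653 against the mean of the controls, 960 against M-D+ and 249 in M-D+ against M-D-. With only the groups compared they were 905 against M-D+, 82 against M-D-, 6 in M+D- against M-D- and 0 in M-D+ against M-D- (1377 at an unadjusted p below 0.05). M+D+ against the 6 control libraries pooled as one group gave 172, and with M-D+ left out of the control average 377. Thinned to the shallowest library, the counts were 159 against M-D-, 90 in M-D+ against M-D- and 17 for the interaction. With the esr1 level as a covariate they were 323 against M+D-, 760 in M-D+ against M-D- and 995 for the interaction. For M-D+ against M-D- a pseudocount of 0.5 gave 225 and a pseudocount of 5 gave 692. With an estimated correlation camera called 0 gene lists, against 5 with the preset correlation.

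With each library left out in turn, counts ran from 67 to 1323 against the mean of the controls, 1057 to 1792 against M-D+, 0 to 261 against M+D-, 0 to 433 against M-D-, 0 to 1 in M+D- against M-D-, 0 to 617 in M-D+ against M-D- and 0 to 511 for the interaction, and from 4 to 9 gene lists. The lone library left in a group is assumed there to vary like the other groups.

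The replicate number as a block gave 727 rows against the mean of the controls, 1699 against M-D+, 48 against M+D-, 85 against M-D-, 0 in M-D+ against M-D- (1547 at an unadjusted p below 0.05), 6 for the interaction, and 5 gene lists. Correlations of the deviations of same-numbered libraries ran from -0.333 (M-D+ and M+D+) to 0.045, so same-numbered libraries showed no clear likeness. The negative value means that differently numbered libraries of M-D+ and M+D+ deviated alike. M-D+ library 1 and M+D+ library 2 also stand together in the split of libraries under other observations. A block by replicate number does not take up such a likeness. With 2 libraries per group this cannot exclude a shared fish, day or batch.

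Opposite signs arose in 28 values of 5 uncalled genes. The values of krt91 with the opposite sign were 0.034 (quantile normalization), 0.062 (equal medians of log values), 0.017 (DESeq2 on recovered tags). The values of esr1 with the opposite sign were 0.64 (without M+D+ library 1). The values of zp3a.1 with the opposite sign were 0.22 (quantile normalization), 0.13 (equal medians of log values), 0.52 (edgeR quasi-likelihood on recovered tags), 1.03 (without M+D+ library 1), 0.14 (M-D- left out of the control average), 0.64 (DESeq2 on recovered tags), 0.49 (esr1 level as a covariate). The values of fabp10a with the opposite sign were -0.19 (without M-D+ library 1), -0.22 (without M+D+ library 1), -0.068 (M-D+ left out of the control average), -0.25 (esr1 level as a covariate). The values of krt4 with the opposite sign were 0.39 (TMM scaling of the values), 0.55 (quantile normalization), 0.57 (equal medians of log values), 0.23 (without the 50 most abundant rows), 0.66 (edgeR quasi-likelihood on recovered tags), 0.08 (without M-D- library 2), 0.15 (without M+D- library 1), 0.02 (without M-D+ library 2), 0.77 (without M+D+ library 1), 0.57 (M-D+ left out of the control average), 0.76 (DESeq2 on recovered tags), 0.43 (without ribosomal protein and fabp10a rows), 0.15 (esr1 level as a covariate). Without M+D+ library 2 the values were -3.235 (esr1, tumour vs mean of 3 controls), -1.939 (zp3a.1, tumour vs mean of 3 controls), 0.313 for fabp10a and -0.81 for krt4, the other end of their ranges over left-out libraries.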

Other observations

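The correlations and the tests of the split of libraries were chosen only after the result was seen.

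Several genes that rose in the tumours also stood higher in transgenic fish without doxycycline than in untreated wild-type fish, though limma called no row in that comparison. The genes here were chosen after their values were seen. Levels of pabpc4 were 971 ± 644 CPM in M+D- and 79.0 ± 4.6 in M-D- (SD, n = 2), a log2 difference of 3.43 with a limma adjusted p of 0.246. Levels in M+D- and M-D- were 48.2 ± 27.9 and 10.4 ± 3.1 for sesn1, 33.1 ± 3.6 and 13.7 ± 4.9 for pgam2, and 14.9 ± 0.2 and 5.1 ± 1.7 for eif4ebp3l. Of these, sesn1 also stood at 24.4 ± 0.8 in M-D+.

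The genotype effects with doxycycline (M+D+ against M-D+) and without it (M+D- against M-D-) share no libraries. Across the 4577 rows their log2 changes had a Pearson r of 0.302 and a Spearman rho of 0.326, and r was 0.312 after TMM scaling. For the doxycycline effects in transgenic and in wild-type fish r was 0.145, and 0.150 after TMM scaling. These are correlations across genes, which are not independent replicates.

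Both M-D- libraries, M-D+ library 1 and M+D+ library 2 stood apart from the other 4 libraries in 5 rows, with at least 5 CPM and a 4-fold gap: cyp2k6, cyp46a1.1, mfap4.4, sec61g and XM_001918615. Levels of sec61g were 137 and 139 in M-D-, 6.17 and 7.29 in M+D-, 279 and 5.89 in M-D+, and 120 and 8.59 in M+D+ libraries 2 and 1. Ovary RNA stays open: the ratio of each row to the zona pellucida tags (zp3a.1 and zp3b) differed at least 3.81 times among those 4 libraries, but the lowest ratio was always that of M-D- library 2. With 1 library left out the ratio differed 1.42 times for sec61g, 1.47 for XM_001918615, 1.98 for cyp46a1.1, 2 for mfap4.4 and 2.14 for cyp2k6, so the rows do not all exceed the bound of 2 times. More female fish behind them stay open too, as 0 vitellogenin rows were found by gene symbol and the labels used give no sex. Only 10410 of 15600 rows had a symbol, so vitellogenin rows without a symbol are not excluded. The estrogen receptor gene esr1, from the female liver list and read after its values were seen, stood at 12.27, 23.85, 128.98 and 20.6 CPM in those 4 libraries and at 0.47 to 8.38 in the others, which goes with that explanation. The division overlaps with genotype among the fish without doxycycline. The split by doxycycline gave 6 such rows, none with a gene symbol, the split by genotype 0, and no other of the 35 splits of the 8 libraries gave more than 5.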
